A study of Caenorhabditis elegans with 94 samples.

How the data were processed

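The 94 libraries were made from whole adult hermaphrodites of C. elegans. Per a protocol deposited alike for every sample, total RNA was extracted with Trizol, spike-in RNA was added, in a smaller amount for OP50 than for RNAi food, and libraries were made with the NEBNext Small RNA kit, with size selection after reverse transcription. No spike-in amount could be assigned to sample groups 3 and 5. Per the labels, reads were aligned with Bowtie, its version and the genome build not given in the sources used here. The deposited count table holds raw counts of 437 microRNA entries per library, of which 35 have no read, and its 10 spike-in entries hold 0 reads. Mapped and total reads per library are deposited as counts. The tail values are deposited as percent, the share of a microRNA's reads with 1 untemplated A, C, G or U at the 3′ end. Per the file headers, microRNAs under 50 RPM are left without a tail value. The authors also gave abundance as RPM, scaled to genome-mapped reads. In the deposited table of sample group 4 the percent and RPM columns carry the unit other, because commas in its heading kept them from being read automatically. A spike-in signal in the table of the upshift course is, per the file headers, scaled to spike-in reads. The class of each RNAi target and the half-lives come from the authors' own tables under the unit other. RPM times mapped reads gave the deposited counts for 100% of the values matched, within 0.05 reads, and 99.93% or more of the A-tail percents gave whole reads.

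Samples were grouped by the labels. Libraries named sKP number 43 and those named sKFV 39. The shared growth protocol speaks of pash-1 animals for the screen, but every screen label gives wild type, which was used. The tail table of wild-type sample group 1 heads its second block with a library name other than that in the labels, and its values differ, so it was left out and 2 wild-type libraries have tails. Tails are available for 81 libraries. The replicate numbers of the cid-1 and F31C3.2 24 h libraries differ between labels and table, and those of the labels were used. Another 120 per-sample columns of these tables were not used, and 5 microRNAs of the wild-type table had no match in the count table. Developmental libraries of other studies were not analysed here. The mRNAs of the RNAi targets are not measured here.

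Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, robust quasi-likelihood F tests and Benjamini-Hochberg adjusted p under 0.05. Each sample group was fitted apart. Groups with 1 library take their spread from the others. Tested microRNAs numbered 243, 225, 192 and 259 in sample groups 1 to 4 and 303 in the screen, with a common biological coefficient of variation of 0.366, 0.408, 0.603, 0.287 and 0.357. Replicates of one group differed by at least 83.6 chi-square units per degree of freedom, so depth is not what limits precision for abundant microRNAs. Tail percents were tested with limma 3.58.1 and robust empirical Bayes, for microRNAs with a mean total count of at least 100: 64, 81, 52 and 92 in sample groups 1 to 4 and 104 in the screen. In sample group 1 48 of them had values in every group and were tested. The mean percent per library was tested by a two-sided exact permutation test, in a family of 48 tests. Correlations across microRNAs used 100000 permutations. Lists of microRNAs were tested by fry and camera where at least 3 members were tested: mirtrons, the let-7, lin-4, mir-35, mir-51, mir-58, mir-64, mir-44, mir-72 and mir-2 families, the markers of muscle (mir-1), intestine (mir-60), neurons (mir-124, mir-790, mir-791, lsy-6) and glia (mir-228), and the minor arms of hairpins, the arm with the lower mean count. The mir-35 list holds 3p arms but for mir-41-5p. The pairs mir-44-3p with mir-45-3p and mir-1829b-3p with mir-1829c-3p share all counts. Positions are from Ensembl release 115 for WBcel235. Other tools were DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

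The comparisons, tests, lists, naming rule and most of the alternative settings were fixed before the data were examined. The naming rule takes, per contrast, up to 12 microRNAs in each direction past an adjusted p of 0.05 with the largest log2 fold change and a mean of at least 10 CPM (counts scaled to the library total times its TMM factor, as is every CPM printed), and for tails up to 12 in each direction with the largest change in points. List members may be named as examples. The rule yields 307 abundance and 391 tailing results, more than the text can hold. The 83 and 61 printed were picked after their values and leave-one-out results had been seen. Results that lose their call without 1 library were mostly passed over, so the printed ones look more stable than the full set, whose stability is given with the alternatives. In the screen the 6 targets with calls are described together with cid-1, gld-2, pup-2 and F31C3.2. The comparison of sample group 5 was chosen after seeing the data.

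The tests were tried on simulated data, with 60 microRNAs changed (20 for tails), fewer than planned as under 400 are tested. Of 4-fold changes edgeR found 16 of 29 for 48 h against 0 h, 15 of 30 for 24 h on L4440, 8 of 30 for pup-1, 29 of 30 for gldr-2 and 20 of 30 for dis-3, and of 2-fold changes 1, 1, 2, 20 and 4. Of changes of 3 points in U tails limma found 9, 10 and 9 of 10 for pup-1, gldr-2 and cid-1 RNAi in the screen, and of 1 point 2, 8 and 4. No call had the wrong sign.

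Alternative settings fixed then were DESeq2, upper quartile scaling, no filter, spike-in scaling for the course of sample group 1, a replicate block, the library prefix as a covariate, each replicate left out, minimum total counts of 20 and 500, a log2 scale with an offset of 0.5, medians and pooled reads per library, and camera with an estimated correlation. Those chosen after seeing the data were merging identical count entries, TMM scaling of the libraries with spike-in reads, the block numbered as in the deposited table, leaving out G tails, the prefix covariate for tails, the block for lists and per library, and all those of sample group 5. Replicate numbers paired the libraries, with every pair correlated over 0.1 and at least 3 pairs, only for gld-2 RNAi (0.277 to 0.543) and for gldr-2 with gld-2 RNAi (0.265 to 0.394) in abundance, in tails for gld-2 RNAi over all tails (0.141 to 0.469) and U tails (0.186 to 0.589) but not A tails (-0.45 to 0.345), and for the pup-1/-2 double mutant over all, A and U tails. The libraries paired in abundance were taken as paired in tails too. In sample groups 1 and 2 there are 2 pairs.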

Results

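Small RNA was sequenced from 94 libraries of whole adult hermaphrodites of C. elegans, and the measurements were the read count of each microRNA and the percent of its reads that carry 1 untemplated nucleotide at the 3′ end, here called a tail. Sample group 1 held 3 wild-type libraries and 2 libraries each of the pash-1(mj100) strain at 0, 6, 24 and 48 h after the shift to the restrictive temperature. This allele makes Pasha, a protein needed to cut primary microRNA transcripts, temperature sensitive. Sample group 2 held pash-1 animals fed bacteria with the empty vector L4440 or a cid-1 or F31C3.2 RNAi clone, at 0 h with 2 libraries each and at 24 h with 2, 2 and 1 libraries. Sample group 3 held 3 libraries each of wild type, the pup-1 mutant, the pup-2 mutant and the pup-1/-2 double mutant. Sample group 4 held 4 libraries each of wild type and the gldr-2 mutant, on L4440 and on gld-2 RNAi. The RNAi screen held 4 L4440 libraries, 2 each for cid-1 and F31C3.2, and 1 for each of 24 other targets. Sample group 5 held 12 libraries. The genes cid-1 and F31C3.2, also called pup-1 and gldr-2, encode nucleotidyltransferases, enzymes that add nucleotides to RNA ends.

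MicroRNA reads per library ran from 283317 to 5252705 in sample group 1, from 2094418 to 7402049 in sample group 2, from 504921 to 3573090 in sample group 3, from 11050305 to 17241109 in sample group 4, from 20119345 to 25362031 in sample group 5 and from 999420 to 18597330 in the screen. MicroRNAs made up 65.6% ± 6.23 (SD, n = 3) of genome-mapped reads in wild type of sample group 1. In pash-1 the share was 45.5% ± 12.9 (SD, n = 2) at 0 h, 47.2% ± 5.02 (SD, n = 2) at 6 h, 31.4% ± 6.72 (SD, n = 2) at 24 h and 8.3% ± 2.26 (SD, n = 2) at 48 h. Values below are log2 fold changes ± SE from edgeR on counts, or changes in percentage points ± SE from limma on tails, with Benjamini-Hochberg adjusted p. No label says that replicates came from separate cultures, so each p measures the spread between these libraries. PCR reads are not independent molecules, so intervals from reads cover counting error only. The microRNAs printed are examples from the longer list of the naming rule, chosen with their leave-one-out results known. Of the 307 abundance results named, 188 kept their call whichever library was left out, against 78 of the 83 printed. Of 284 tailing results named and recomputed, 54.6% kept it, against 45 of the 61 printed.

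The first comparison asked how pash-1 animals before the shift differed from wild type, 2 libraries against 3. The mir-35 family, made in oocytes and embryos and needed for embryonic development, fell in all 8 members, with a median of -4.30. Its member mir-35-3p, encoded on chromosome II at 11537608 to 11537704 of WBcel235, fell by 5.80 ± 0.45 (adjusted p = 8.25e-07, edgeR), from 55826 ± 18889 CPM (SD, n = 3) to 1001 ± 408 (SD, n = 2). The other arm of mir-39, mir-39-5p, fell by 5.10 ± 0.84. Among heterochronic microRNAs, which time larval development, lin-4-5p rose by 2.12 ± 0.32 (adjusted p = 0.000163, edgeR) to 6822 CPM and mir-84-5p rose by 2.12 ± 0.34. Rises were also seen for mir-4920, by 4.46 ± 0.52, and mir-1829a-5p, by 2.34 ± 0.31. Of mirtrons, microRNAs released by splicing without Pasha, 2 of 3 tested rose, with a median of 1.88. In total 60 microRNAs were higher and 86 lower of 243 tested.

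By list, this comparison called 3 higher and 2 lower of 8 let-7 family members, 1 and 1 of 2 in the lin-4 family, 2 and 2 of 6 in the mir-51 family, 3 and 1 of 5 in the mir-58 family, 1 and 3 of 4 in the mir-64 family, 3 and 1 of 4 in the mir-44 family, 1 and 1 of 3 in the mir-72 family and 1 and 1 of 3 in the mir-2 family. The median and mean differ in sign for the let-7 family (0.88 and -0.90), the mir-51 family (0.57 and -0.08) and the mir-44 family (1.00 and -0.08). The muscle microRNA mir-1-3p rose by 1.26 ± 0.39, a call lost by DESeq2 (1.12) and without 0 h replicate 1 (1.25), 0 h replicate 2 (1.12), wild-type replicate 2 (0.87) or wild-type replicate 3 (0.84). The intestinal mir-60-3p, at 0.86, and the glial mir-228-5p, at 0.36, did not pass. Neuronal microRNAs had 1 higher and 2 lower of 4, and the minor arms of hairpins 7 higher and 29 lower of 79. Adjusted over the list alone, counts were the same in every list but the minor arms, where 27 were lower. In the fry test, adjusted p was 0.0027 for the mir-35 family and for mirtrons. The camera test gave adjusted p = 0.00628 for the mir-35 family and adjusted p = 0.2655 for mirtrons with its preset correlation, and adjusted p = 0.615 for each with an estimated correlation. The groups differ in strain, and upper quartile scaling moved the median of all microRNAs from -0.25 to -0.01.

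Tails of the same pash-1 animals at 0 h were compared with 2 wild-type libraries. The U tails of mir-64-5p dropped by 7.10 ± 0.941 points, from 11.7% ± 1.1 (SD, n = 2) to 4.6% ± 1.84 (SD, n = 2), with adjusted p = 0.00512 from limma. Those of mir-46-3p dropped by 1.77 ± 0.172 points. U tails of mir-48-5p, a let-7 family member, rose by 0.817 ± 0.197 points, and A tails of mir-66-5p dropped by 0.236 ± 0.036 points. Of 48 microRNAs tested, 9 changed in U tails, with 1 higher and 8 lower, and 1 changed in A tails. The mean U tail percent per library was 1.00% ± 0.0486 (SD, n = 2) against 1.73% ± 0.0316 (SD, n = 2), with a two-sided exact permutation p = 0.333, the smallest that 2 against 2 allows. Leaving out 0 h replicate 1, 0 h replicate 2 or wild-type replicate 1 brought the U count to 3, 5 and 5. The mir-48-5p call was lost without any 1 library (0.727 to 0.907 points), and the A call was lost without 0 h replicate 2 or wild-type replicate 3 (-0.202 points).

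The course after the shift asked which microRNAs decayed once production stopped. At 6 h, mir-34-3p fell by 4.31 ± 0.60 (adjusted p = 0.00105, edgeR) and mir-253-3p fell by 2.34 ± 0.55. At 24 h, mir-253-3p fell by 3.18 ± 0.57, mir-61-3p by 2.49 ± 0.38, mir-250-3p by 2.11 ± 0.45 and mir-235-3p by 2.62 ± 0.37, the last from 6478 ± 1050 to 1056 ± 168 CPM (SD, n = 2 each). At 48 h, mir-235-3p fell by 3.98 ± 0.39 (adjusted p = 4.69e-06, edgeR), mir-78 by 2.60 ± 0.41 and mir-61-3p by 2.20 ± 0.37. The called counts were 11 at 6 h (8 higher, 3 lower), 69 at 24 h (47 higher, 22 lower) and 77 at 48 h (48 higher, 29 lower) of 243 tested.

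Of the 3 mirtrons 2 rose in the course. mir-62, encoded on chromosome X at 12692608 to 12692665 within ugt-50, rose by 3.47 ± 0.60 at 24 h and by 4.66 ± 0.63 at 48 h (adjusted p = 9.68e-05, edgeR), from 518 ± 140 to 13084 ± 9690 CPM (SD, n = 2). mir-1018 rose by 4.77 ± 0.48 at 24 h and by 6.42 ± 0.51 at 48 h, and mir-1020-3p was at 0.50 ± 0.38 and not called at 48 h. The mirtron medians were 3.47 and 4.66, with fry adjusted p of 0.000485 and 0.00023. Camera adjusted p was 0.123, and 0.793 with an estimated correlation. Outside the mirtron list, mir-4807 rose by 5.05 ± 0.50 at 24 h and by 6.21 ± 0.52 at 48 h, mir-4808-3p by 7.11 ± 0.71 at 48 h and mir-44-5p by 5.61 ± 0.70 at 24 h. In the mir-35 family 5 of 8 rose at each of 24 and 48 h, with mir-38-3p at 3.94 ± 0.78 and 4.64 ± 0.80, and the fry adjusted p was 0.173. Adjusted over the list alone, 6 rose at 48 h. Intestinal mir-60-3p rose by 2.42 ± 0.70 at 48 h, but was at -0.16 without 48 h replicate 1.

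These rises are relative to the other microRNAs, whose total fell. Per spike-in read there were 1736 and 2205 microRNA counts at 0 h, 1340 and 1295 at 6 h, 606 and 1171 at 24 h, and 336 and 738 at 48 h. In the pash-1 libraries, over the same 202 microRNAs, scaling to the spike-in in place of TMM moved the median from 0.12 to -0.39 at 6 h, from 0.14 to -0.67 at 24 h and from 0.35 to -1.38 at 48 h. It called 8 higher and 3 lower at 6 h (12 and 3 with TMM), 31 higher and 42 lower at 24 h (50 and 24), and 23 higher and 99 lower at 48 h (54 and 31). Under it mirtrons kept medians of 2.49 at 24 h and 2.68 at 48 h, the mir-35 family had medians of 1.27 and 0.27, and mir-1020-3p was at -1.26 at 48 h. Upper quartile scaling put the medians of all microRNAs at -0.33, -0.31 and -0.29. The 6 h count of 11 was 1 without 0 h replicate 1, 0 h replicate 2 or 6 h replicate 1, and the 6 h call of mir-253-3p was lost without any 1 library (-2.98 to -1.54). The 24 h count was 40, 44 and 39 without 0 h replicate 1, 0 h replicate 2 and 24 h replicate 1, and the 48 h count was 36 and 48 without 0 h replicate 1 and 48 h replicate 1. Animals at later times were also older and had been longer at the restrictive temperature, and no wild-type animals were shifted.

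U tails of several microRNAs rose along the course. mir-70-3p, encoded on chromosome V at 6665536 to 6665635 within pmp-5, went from 4.17% ± 0.285 at 0 h to 12.05% ± 1.21 at 24 h and 18.3% ± 3.13 at 48 h (SD, n = 2 each), a rise of 14.1 ± 1.42 points at 48 h (adjusted p = 0.00111, limma). mir-71-5p, a microRNA that extends lifespan in adults, rose by 2.98 ± 0.33 points at 24 h and 4.53 ± 0.33 at 48 h. mir-48-5p rose by 2.51 ± 0.197 points at 6 h, 4.1004 ± 0.197 at 24 h and 3.63 ± 0.197 at 48 h. In the mir-35 family mir-40-3p rose by 2.81 ± 0.419 points at 24 h, whereas mir-35-3p dropped by 0.759 ± 0.186 and mir-39-3p dropped by 1.28 ± 0.365 at 48 h. Of 48 tested, 1, 4 and 18 microRNAs changed in U tails at 6, 24 and 48 h, the first 2 sets all higher and the last with 16 higher and 2 lower. In A tails limma called 0 at 6 h (0 at an unadjusted p under 0.05), 0 at 24 h (4 unadjusted) and 4 at 48 h. Mean U tails per library were 1.25% ± 0.158 at 6 h, 1.51% ± 0.0166 at 24 h and 1.98% ± 0.0862 at 48 h (SD, n = 2 each), each with exact permutation p = 0.333, the smallest possible. The 24 h count of 4 was 2 without 0 h replicate 2, 24 h replicate 1 or 24 h replicate 2. There the calls of mir-70-3p (7.02 to 8.74) and mir-40-3p (2.60 to 2.93) were lost without single libraries. The 48 h U count was 9 and 8 without 0 h replicates 1 and 2, which also ended the falls of mir-35-3p (-0.805 to -0.557) and mir-39-3p (-1.60 to -0.970), and the 48 h A count was 0 without either 0 h library and 7 without 48 h replicate 1.

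Sample group 2 asked whether decay differed when a tailing enzyme was knocked down. On L4440, 24 h after the shift, mir-62 rose by 3.25 ± 0.45 (adjusted p = 0.00228, edgeR), from 1458 ± 749 to 13911 ± 97.3 CPM (SD, n = 2 each). mir-1018 rose by 4.31 ± 0.61, mir-4807 by 3.76 ± 0.60 and mir-67-5p by 3.93 ± 0.62, while mir-61-3p fell by 2.37 ± 0.28, mir-253-3p by 3.34 ± 0.59 and mir-34-3p by 3.24 ± 0.56. On cid-1 RNAi mir-61-3p fell by 2.15 ± 0.28 and mir-253-3p by 3.28 ± 0.59, and on F31C3.2 RNAi mir-61-3p fell by 3.10 ± 0.39 and mir-1018 rose by 4.33 ± 0.65. In each of the 3 arms 2 of 3 mirtrons rose, with medians of 3.25, 2.93 and 2.11 and fry adjusted p of 0.0257, 0.0257 and 0.0382, but camera adjusted p of 0.101, 0.203 and 0.206, and adjusted p of 0.753 in each with an estimated correlation. In the mir-35 family 0 of 8 changed on L4440, 5 rose on cid-1 RNAi (6 adjusted over the list alone) and 1 on F31C3.2 RNAi. On cid-1 RNAi mir-38-3p rose by 4.74 ± 0.80, mir-36-3p by 3.64 ± 0.76 and mir-44-5p by 5.27 ± 0.86. Camera there gave the mir-35 family adjusted p = 0.024, and adjusted p = 0.753 with an estimated correlation.

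Of 225 tested, 44 changed on L4440 (37 higher, 7 lower), 57 on cid-1 RNAi (42 higher, 15 lower) and 31 on F31C3.2 RNAi (25 higher, 6 lower). The difference between foods was tested directly, on counts with TMM scaling, which sets each microRNA against the others. A faster or slower decay of all microRNAs alike could not show in this test. For cid-1 RNAi against L4440 edgeR called 0 microRNAs, with 12 at an unadjusted p under 0.05 and 2 by DESeq2, and for F31C3.2 RNAi it called 0, with 9 unadjusted and 0 by DESeq2. The L4440 count was 18, 10 and 20 without 0 h replicate 1, 0 h replicate 2 and 24 h replicate 2. On F31C3.2 RNAi it was 15 and 8 without 0 h replicates 1 and 2, and 54 by DESeq2. The cid-1 difference was 3 without L4440 0 h replicate 2 and 8 without cid-1 0 h replicate 2, and the F31C3.2 difference was 1 without F31C3.2 0 h replicate 1. F31C3.2 had 1 library at 24 h, which was assumed to vary like the other groups.

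U tails rose in this course as well. On L4440 mir-71-5p went from 0.897% ± 0.206 to 3.14% ± 0.381 (SD, n = 2 each), a rise of 2.24 ± 0.188 points (adjusted p = 0.00274, limma), mir-70-3p rose by 6.86 ± 1.34 points and mir-48-5p by 1.57 ± 0.279. On cid-1 RNAi mir-71-5p rose by 1.47 ± 0.188 points, and on F31C3.2 RNAi by 2.53 ± 0.23. On F31C3.2 RNAi mir-253-3p rose by 8.33 points, from 1.35% ± 0.466 (SD, n = 2) to 9.68% in the single 24 h library, where 6 of 62 reads carried one (95% Wilson interval 4.51% to 19.5%). In that microRNA the change exceeded that on L4440 by 9.47 points, a call that rests on these 6 reads, whose counting error the limma SE leaves out. Of 81 tested, 5, 1 and 7 microRNAs rose in U tails on L4440, cid-1 RNAi and F31C3.2 RNAi, and limma called 0 in A tails, with 1, 9 and 2 at an unadjusted p under 0.05. The test of the difference called 0 for cid-1 RNAi (7 unadjusted) and 1 for F31C3.2 RNAi in U tails, and 0 for cid-1 RNAi in A tails (6 unadjusted). The L4440 count was 3 and 2 without 0 h replicates 1 and 2. The mir-70-3p (6.09 to 7.62) and mir-48-5p (1.56 and 1.59) calls there were lost without single libraries. The cid-1 call of mir-71-5p was lost without single libraries (1.45 to 1.501). The F31C3.2 count was 2 without 0 h replicate 2, and its difference from L4440 was 3 without F31C3.2 0 h replicate 1 and 5 without L4440 24 h replicate 2.

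At 0 h, before decay, cid-1 RNAi lowered U tails in pash-1 animals. mir-38-3p dropped by 9.501 ± 1.33 points (adjusted p = 0.0212, limma), from 10.97% to 1.47%, mir-58a-3p dropped by 1.16 ± 0.126, mir-56-3p by 1.09 ± 0.167 and mir-35-3p by 0.625 ± 0.116. These were the 4 changed of 81. F31C3.2 RNAi lowered the A tails of mir-240-3p by 2.46 ± 0.251 points (adjusted p = 0.00589, limma), from 2.85% ± 0.021 to 0.392% ± 0.143 (SD, n = 2 each), which was the 1 called (11 at an unadjusted p under 0.05), and limma called 0 in U tails (8 unadjusted). Mean U tails per library were 1.11% ± 0.114 on cid-1 RNAi against 1.78% ± 0.149 on L4440, and mean A tails were 0.243% ± 0.0106 on F31C3.2 RNAi against 0.568% ± 0.0482 (SD, n = 2 each). In abundance mir-38-3p fell by 4.87 ± 0.81 (adjusted p = 0.0303, edgeR), mir-35-3p by 3.75 ± 0.72 and mir-37-3p by 2.95 ± 0.59 on cid-1 RNAi. Those were the 3 called, all of the mir-35 family, in which adjusted over the list alone 7 of 8 were lower. Its median was -2.83, with fry adjusted p = 0.145, camera adjusted p = 6.06e-09 and adjusted p = 0.377 with an estimated correlation. On F31C3.2 RNAi edgeR called 0, with 17 unadjusted and 1 by DESeq2.

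These 0 h counts rest on single libraries. The U count on cid-1 RNAi was 2 and 0 without L4440 replicates 1 and 2, and 0 without cid-1 replicate 2. The A call of mir-240-3p was lost without single libraries (-2.35 and -2.47). The abundance count of 3 was 0 without L4440 replicate 1 or cid-1 replicate 1, 6 without L4440 replicate 2 and 29 without cid-1 replicate 2. Without L4440 replicate 1 and without cid-1 replicate 1 the values were -3.30 and -4.35 for mir-38-3p, -2.74 and -3.01 for mir-35-3p and -1.89 and -2.46 for mir-37-3p. The abundance count of 0 on F31C3.2 RNAi was 1 without F31C3.2 replicate 1 or L4440 replicate 2.

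Sample group 3 asked whether pup-2 shares the role of its paralog pup-1. The labels write pup-1 and the double mutant over the balancer qC1 and pup-2 without one. The shared protocol has all 3 over a balancer and RNA from homozygous animals. In the pup-1 mutant U tails of mir-77-5p dropped by 5.28 ± 0.527 points (adjusted p = 8.58e-05, limma), from 5.52% ± 0.937 to 0.233% ± 0.203 (SD, n = 3 each). U tails of mir-70-3p dropped by 9.05 ± 1.63 points, those of mir-55-3p, on chromosome X at 13144827 to 13144924, by 8.11 ± 1.33 and those of mir-41-5p by 3.21 ± 0.2001. In the double mutant mir-80-5p dropped by 10.5 ± 1.72 points, mir-64-5p by 9.79 ± 2.43, mir-70-3p by 9.66 ± 1.63, mir-55-3p by 8.58 ± 1.33, mir-77-5p by 5.26 ± 0.527 and mir-41-5p by 3.33 ± 0.2001. Of 52 microRNAs, 10 fell in U tails in the pup-1 mutant and 12 in the double mutant, and limma called 0 in the pup-2 mutant, with 2 at an unadjusted p under 0.05. Mean U tails per library were 3.09% ± 0.310 in wild type, 2.07% ± 1.02 in pup-1, 3.396% ± 0.978 in pup-2 and 1.38% ± 0.185 in the double mutant (SD, n = 3 each), with exact permutation p of 0.3, 0.9 and 0.1, where 0.1 is the smallest possible.

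**Figure D1:**
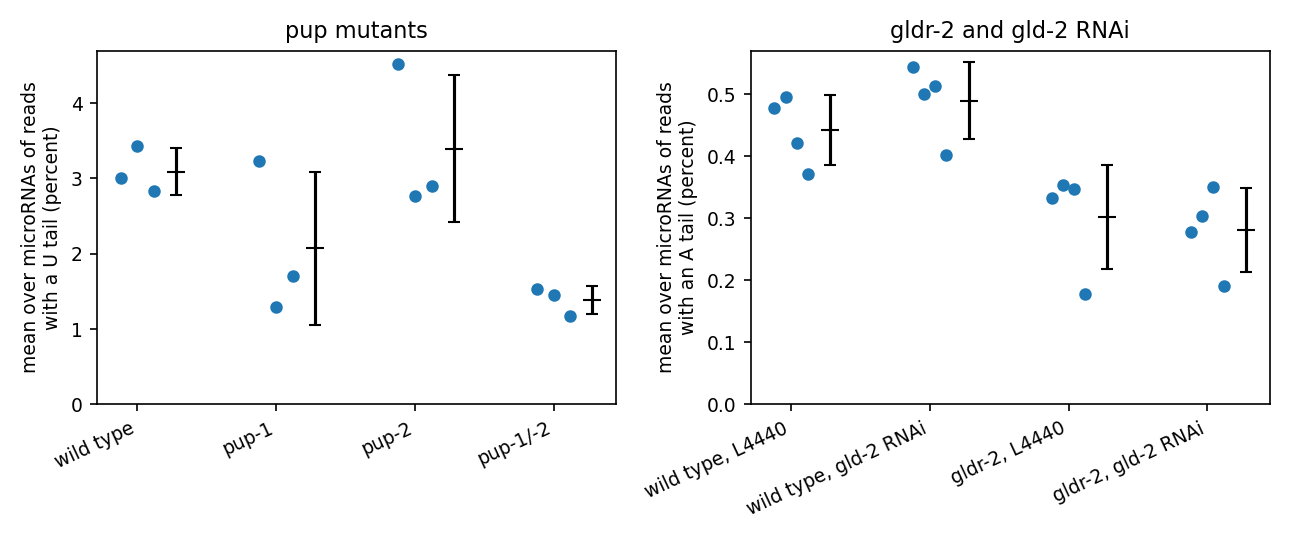
Mean percent of U tails in the pup mutants and of A tails under gldr-2 and gld-2 loss, with points for libraries and bars for the mean ± SD. U tails are lowest in the pup-1/-2 double mutant, at 1.38%, and A tails are lower in gldr-2 animals, at 0.302%, than in wild type, at 0.442%.

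A tails gave 0 calls in the pup-1, pup-2 and double mutants (1, 1 and 0 at an unadjusted p under 0.05, limma). Mean A tails had SDs of 1.26, 1.17 and 0.11 points (0.25 in wild type), which limits the single-mutant tests. The 4 called over all tails in the double mutant were lower. That count was 1 without double-mutant replicate 3 and 2 without wild-type replicate 1. The test of whether the double mutant departs from the sum of the single mutants called 0 in U, all and A tails (0, 0 and 2 unadjusted). In abundance edgeR called 0 of 192 microRNAs in the pup-1, pup-2 and double mutants and for that departure, with 9, 13, 11 and 20 at an unadjusted p under 0.05 and 0, 4, 0 and 0 by DESeq2. Of simulated 4-fold changes the pup-1 test found 8 of 30.

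Sample group 4 asked whether gld-2 shares the role of its paralog gldr-2. In the gldr-2 mutant on L4440 A tails of mir-58a-3p dropped by 0.924 ± 0.0583 points (adjusted p = 5.86e-08, limma), from 1.15% ± 0.0807 to 0.227% ± 0.102 (SD, n = 4 each). A tails of mir-240-3p dropped by 2.17 ± 0.196 points, of mir-250-3p by 1.62 ± 0.136, of mir-254-3p by 1.55 ± 0.186 and of mir-55-3p by 0.691 ± 0.0618. gld-2 RNAi in wild type lowered A tails of mir-64-5p by 0.455 ± 0.0454 points and mir-65-5p by 0.556 ± 0.0615, and raised those of mir-35-3p by 0.350 ± 0.0544. With both, A tails of mir-240-3p dropped by 2.32 ± 0.196 points, mir-250-3p by 1.74 ± 0.136 and mir-58a-3p by 0.930 ± 0.0583. U tails rose for mir-51-5p in gldr-2, by 3.08 ± 0.553 points, and with both, by 4.39 ± 0.553, for mir-61-3p in gldr-2, by 2.403 ± 0.425, for mir-35-3p on gld-2 RNAi, by 0.615 ± 0.108, and for mir-36-3p with both, by 3.46 ± 0.612.

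Of 92 microRNAs A tails changed in 16 in gldr-2 (all lower), 3 on gld-2 RNAi (1 higher, 2 lower) and 16 with both (all lower), and U tails in 4 (3 higher, 1 lower), 5 (4 higher, 1 lower) and 13 (10 higher, 3 lower). With replicate numbers as a block the A counts on gld-2 RNAi and with both were 9 and 26. The interaction of gldr-2 and gld-2 called 0 in A tails and 0 in U tails by limma, with 3 and 4 at an unadjusted p under 0.05. Mean A tails per library were 0.442% ± 0.0564 in wild type, 0.302% ± 0.0839 in gldr-2, 0.489% ± 0.0616 on gld-2 RNAi and 0.281% ± 0.0669 with both (SD, n = 4 each), with two-sided exact permutation p of 0.0286, 0.257 and 0.0286, where 0.0286 is the smallest possible and 0.343 is its adjusted value over 48 tests. Over pairs of the same number the exact permutation p with both was 0.125. Over the median microRNA in place of the mean, the A differences were -0.04 and -0.04 points and did not pass. The A count in gldr-2 was 10 without gldr-2 replicate 4 or wild-type replicate 1. The U count in gldr-2 was 2, 7 and 10 without gldr-2 replicates 1, 2 and 4 and 2 without wild-type replicate 3. On gld-2 RNAi it was 3 without replicate 4, and with both 7 without double-treated replicate 1 or wild-type replicate 2.

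In abundance the gldr-2 mutant had less of the mir-35 family, with 7 of 8 lower and a median of -1.69, and gldr-2 with gld-2 RNAi had 7 of 8 lower and a median of -1.96. mir-42-3p, encoded on chromosome II at 11889811 to 11889905, fell by 2.51 ± 0.42 in gldr-2 (adjusted p = 0.000588, edgeR), from 1138 ± 648 to 200 ± 117 CPM (SD, n = 4 each), by 2.95 ± 0.43 on gld-2 RNAi and by 3.52 ± 0.44 with both. mir-36-3p fell by 2.01 ± 0.44 in gldr-2 and by 2.42 ± 0.45 with both, and mir-38-3p by 3.32 ± 0.59 with both. mir-44-5p fell by 3.18 ± 0.56, 3.52 ± 0.57 and 3.92 ± 0.58 in the 3 comparisons, and mir-4813-5p by 3.80 ± 0.56 in gldr-2 and 3.84 ± 0.56 on gld-2 RNAi. mir-58c rose by 1.05 ± 0.21, 1.40 ± 0.21 and 1.62 ± 0.21. On gld-2 RNAi mir-54-5p fell by 2.35 ± 0.34 and mir-73-5p by 2.14 ± 0.35, and mir-61-3p rose by 0.55 ± 0.13.

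Members of the let-7 family, which time larval development, were higher with both, 7 of 8, with a median of 0.64, and lay above 0 in gldr-2 and on gld-2 RNAi, with 1 and 2 called. With both, mir-84-5p rose by 0.61 ± 0.16, from 4816 ± 1237 to 7375 ± 627 CPM (SD, n = 4 each), mir-241-5p by 0.55 ± 0.17 and let-7-5p by 0.50 ± 0.18, and mir-48-5p was at 0.36 ± 0.21 and not called. The let-7-5p call was lost without double-treated replicates 1 (0.42) or 3 (0.46) or wild-type replicates 1 (0.53) or 2 (0.36), and the mir-241-5p call without double-treated replicate 1 (0.48) or wild-type replicates 1 (0.52) or 2 (0.50). Adjusted over the list alone 7 let-7 members were higher in gldr-2 and 3 on gld-2 RNAi. The tissue markers mir-1-3p (muscle), mir-60-3p (intestine) and mir-228-5p (glia) were at 0.11 ± 0.14, 0.13 ± 0.15 and 0.35 ± 0.20 in gldr-2 and not called, though mir-228-5p passed at 0.51 without gldr-2 replicate 4. Fry adjusted p in gldr-2 was 0.0111 for the mir-35 family and 0.0236 for the let-7 family, with camera adjusted p of 0.00162 and 0.00262, and adjusted p of 0.545 and 0.541 with an estimated correlation.

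Minor arms of hairpins had 29 lower and 2 higher of 87 in gldr-2, 23 lower on gld-2 RNAi and 30 lower with both. Of 259 microRNAs, 70 changed in gldr-2 (15 higher, 55 lower), 51 on gld-2 RNAi (8 higher, 43 lower) and 84 with both (23 higher, 61 lower), by edgeR. With replicate numbers as a block the gld-2 RNAi count was 79. Upper quartile scaling moved the median of all microRNAs to 0.20 in gldr-2, 0.13 on gld-2 RNAi and 0.20 with both, and there 42 were higher and 46 lower in gldr-2. The interaction called 16 microRNAs, all above 0, with mir-54-5p at 2.34 ± 0.46 (adjusted p = 0.013, edgeR), and 14 were minor arms. That count was 0 and 4 without gldr-2 L4440 replicates 1 and 3, 3, 2 and 5 without wild-type gld-2 RNAi replicates 1, 3 and 4, and 5, 3, 5 and 5 without each of the double-treated replicates. It was 9, 8 and 25 without wild-type L4440 replicates 1, 2 and 3, and the mir-54-5p call was lost without gldr-2 L4440 replicate 1 (2.38).

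The screen asked which knockdowns change tailing. cid-1 RNAi lowered U tails of mir-38-3p by 16.9 ± 1.17 points (adjusted p = 0.000642, limma), from 19.3% ± 1.52 on L4440 (SD, n = 4) to 2.38% ± 0.725 (SD, n = 2). U tails of mir-58a-5p dropped by 13.6 ± 1.16 points, of mir-64-5p by 8.14 ± 0.938, of mir-55-3p by 6.45 ± 0.460 and of mir-58a-3p by 4.25 ± 0.362. A tails rose on cid-1 RNAi for mir-35-3p, by 1.502 ± 0.152 points, and for mir-39-3p, by 0.960 ± 0.0963. F31C3.2 RNAi lowered A tails of mir-250-3p by 2.19 ± 0.255 points, from 3.17% ± 0.275 (SD, n = 4) to 0.981% ± 0.220 (SD, n = 2), and of mir-58a-3p by 0.712 ± 0.049. Of the microRNAs tested 36 were lower in U tails and 4 higher in A tails on cid-1 RNAi, and 11 were lower in A tails on F31C3.2 RNAi.

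**Figure D2:**
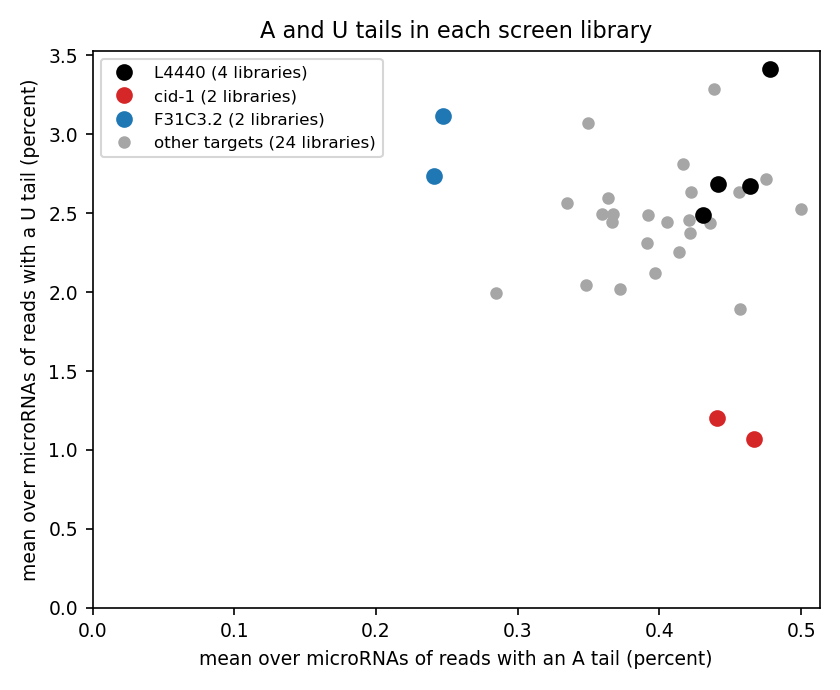
Mean percent of U tails and of A tails over microRNAs for each screen library, with 1 point per library. The 2 cid-1 libraries average 1.14% U tails and the 4 L4440 libraries 2.81%, and the 2 F31C3.2 libraries average 0.244% A tails against 0.453%.

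Mean U tails per library were 1.14% ± 0.0962 (SD, n = 2) on cid-1 RNAi against 2.81% ± 0.408 (SD, n = 4) on L4440, and mean A tails were 0.244% ± 0.00437 (SD, n = 2) on F31C3.2 RNAi against 0.453% ± 0.0213 (SD, n = 4), each with a two-sided exact permutation p = 0.0667, the smallest possible. Within the sKP and sKFV library prefixes, the cid-1 difference in U tails was -1.55 and -2.21 points and the F31C3.2 difference in A tails -0.204 and -0.230. The other targets had 1 library each. Over all tails gld-2 RNAi had 47 higher and pup-2 RNAi 42 higher and 1 lower, and without G tails limma called 0 and 0. Of 28 libraries, 20 lay below the L4440 range in mean A tails and 15 in mean U tails, so a low value alone does not mark a target. In U tails exos-4.1 had 5 called, tsn-1 2 and pap-1 1. The cid-1 U count was 23 without L4440 replicate 2, and 10 and 16 without cid-1 replicates 1 and 2, and its A count was 1 without cid-1 replicate 2, where mir-35-3p was at 1.39 and not called. The F31C3.2 A count was 1 without either F31C3.2 library, and 7 and 6 without L4440 replicates 1 and 2. Without F31C3.2 replicates 1 and 2 the call of mir-250-3p was lost (-2.04 and -2.35).

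In abundance dis-3, exos-4.1 and pap-1 RNAi, 1 library each against 4 of L4440, gave most changes in the screen. dis-3 and exos-4.1 encode parts of the exosome, which degrades RNA from the 3′ end, and pap-1 encodes a poly(A) polymerase. The mir-35 family had 7 of 8 members lower in each, with medians of -5.24, -5.16 and -4.36, and 6 of 8 lower on dcs-1 RNAi, the scavenger decapping enzyme (7 adjusted over the list alone). mir-35-3p fell by 5.26 ± 0.74 (adjusted p = 0.00151, edgeR) on dis-3 RNAi, to 1440 (95% Wilson interval 1419 to 1461) from 55266 ± 20312 CPM (SD, n = 4), by 5.24 ± 0.74 on exos-4.1, 4.399 ± 0.70 on pap-1 and 3.89 ± 0.68 on dcs-1 RNAi. Of other members mir-41-5p was at -5.63 ± 0.78 on dis-3 and -6.10 ± 0.80 on exos-4.1, mir-37-3p at -5.23 ± 0.93 on dis-3 and mir-40-3p at -4.46 ± 0.83 on dcs-1 RNAi. The member that did not fall was mir-42-3p, at 1.25 ± 0.92 on dis-3 and 1.76 ± 0.90 on exos-4.1 RNAi, not called, though it passed as higher without L4440 replicate 1 (1.99 and 2.48) and on exos-4.1 with upper quartile scaling (2.18). Fry adjusted p was 0.0793, 0.0793, 0.0971 and 0.166 for the 4, camera adjusted p 4.03e-05, 1.28e-05, 5.1e-06 and 1.36e-07, and unadjusted p 0.0874, 0.0719, 0.0635 and 0.0406 with an estimated correlation (adjusted p = 0.98 in each).

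**Figure D3:**
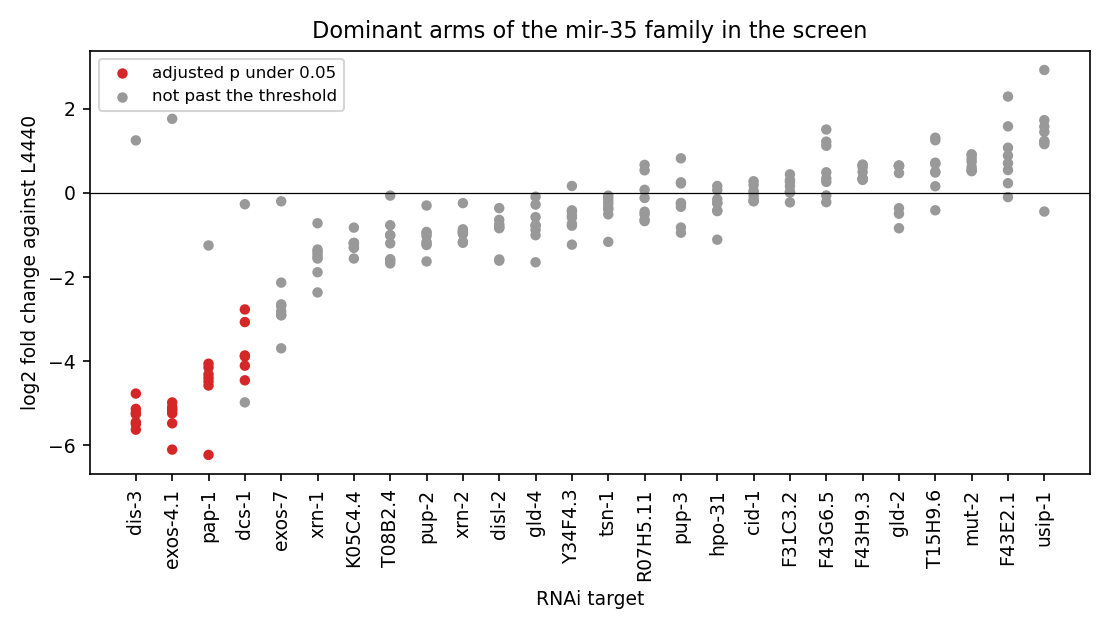
Log2 fold change of the mir-35 family members against L4440 for each screen target. The family medians are -5.24, -5.16, -4.36 and -3.88 on dis-3, exos-4.1, pap-1 and dcs-1 RNAi.

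Other microRNAs rose in these libraries. mir-788-5p, encoded on chromosome X at 8485294 to 8485371, rose by 7.41 ± 0.97 on dis-3 and 6.87 ± 0.96 on exos-4.1 RNAi, let-7-3p, the minor arm of let-7, by 5.40 ± 0.77 and 5.65 ± 0.77, and mir-247-3p by 3.62 ± 0.54 and 3.22 ± 0.55. mir-359 fell by 3.99 ± 0.45 on dis-3 RNAi. lin-4-5p rose by 1.48 ± 0.32 on exos-4.1 and 1.85 ± 0.32 on pap-1 RNAi, where mir-237-5p rose by 1.73 ± 0.30, mir-228-3p by 2.69 ± 0.45 and mir-2208a-5p by 5.05 ± 0.73. On RNAi of xrn-2, a nuclear 5′ to 3′ exonuclease, mir-2208a-5p rose by 6.66 ± 0.74 (adjusted p = 0.00128, edgeR), mir-239b-5p by 4.06 ± 0.58, mir-2208b-5p by 3.83 ± 0.56 and mir-2209a-3p by 3.25 ± 0.50. On RNAi of its cytoplasmic counterpart xrn-1 mir-229-3p rose by 2.19 ± 0.30, to 1243 (95% Wilson interval 1226 to 1260) from 271.6 ± 31.8 CPM (SD, n = 4). Of 303 microRNAs, 65 changed on dis-3 (25 higher, 40 lower), 49 on exos-4.1 (18 higher, 31 lower), 47 on pap-1 (20 higher, 27 lower), 13 on dcs-1 (4 higher, 9 lower), 8 on xrn-2 (all higher) and 1 on xrn-1 RNAi. edgeR called 0 for cid-1, gld-2, pup-2 and F31C3.2 RNAi, with 14, 9, 11 and 4 at an unadjusted p under 0.05.

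Each of these screen targets borrows its spread from the replicated groups. By name, the dis-3, exos-4.1, pap-1 and xrn-1 libraries have the highest numbers of the sKP screen libraries, above every sKP L4440 library. The labels do not say whether they were prepared together, and the prefix covariate cannot correct for that. With the library prefix as a covariate 45 were higher and 61 lower for dis-3, and the counts were 77, 83 and 15 for exos-4.1, pap-1 and xrn-2 and 2 for xrn-1, and 11 targets had at least 1 call against 6. The exos-4.1 count was 30 without L4440 replicate 2, and the dcs-1 count was 5, 7 and 5 without L4440 replicates 2, 3 and 4 and 21 by DESeq2. Upper quartile scaling gave 13 for xrn-2 and 2 for xrn-1.

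Changes were then compared between sets of libraries, across microRNAs, which are not independent replicates, in a family of 9 relations. Falls in points are bounded by the tails in the controls, so the relations of U and A tail changes under knockdown partly follow from those tails. U tail changes on cid-1 RNAi in the screen and in the pup-1 mutant had a Pearson r of 0.840 and a Spearman rho of 0.610 over 52 microRNAs, each with a permutation p of 1e-05, the smallest possible, and adjusted p of 1.5e-05 and 1.8e-05. Without the 2 farthest microRNAs r was 0.740. On cid-1 RNAi in the screen and in pash-1 at 0 h, r was 0.803 and rho 0.706 over 75 microRNAs, and r was 0.549 without the 2 farthest. A tail changes on F31C3.2 RNAi in the screen and in the gldr-2 mutant had an r of 0.834 and a rho of 0.348 over 89 microRNAs, with permutation p of 1e-05 and 0.00086 (adjusted 1.5e-05 and 0.0013), and r was 0.682 without mir-240-3p and mir-250-3p. On F31C3.2 RNAi in the screen and in pash-1 at 0 h, r was 0.772 and rho 0.576, and r was 0.515 without the same 2. Log2 fold changes at 24 h in sample groups 1 and 2 had an r of 0.752 and a rho of 0.827 over 213 microRNAs, and r was 0.765 without the 2 farthest, and U tail changes at 24 h an r of 0.832 and a rho of 0.704 over 48. Of 213 microRNAs tested at 24 h in sample group 1 and on L4440 in sample group 2, 30 were higher in both against 8.16 for independent lists (Fisher's exact p = 4.6e-18, two-sided) and 7 were lower in both against 0.657 (Fisher's exact p = 2.2e-08).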

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

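In this part the tests on G tails, the mir-35 family and all 7 minor arms and the splits of the samples were chosen only after the results were seen. The tests of mir-44-5p against oocyte content and depth were written before.

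In the screen the gld-2 RNAi library had a mean of 2.24% G tails, against 0.132% ± 0.0103 (SD, n = 4) on L4440, and 10 of 28 libraries lay above the highest L4440 value of 0.138%. The others were pup-2 (1.37%), R07H5.11 (0.789%), T08B2.4 (0.708%), cid-1 replicate 1 (0.589%), K05C4.4 (0.547%), F43G6.5 (0.261%), T15H9.6 (0.171%), hpo-31 (0.164%) and tsn-1 (0.149%). In the gld-2 library loss of the target is argued against, since wild-type gld-2 RNAi libraries of sample group 4 had 0.103% G tails, and so is a single failed cycle, since the excess varied by a factor of only 1.68 over microRNA lengths, but in K05C4.4 and F43G6.5 it varied by 3.365 and 3.196, which leaves a failed cycle open there. A library step that adds or misreads a G in every read may account for the gld-2 library, with 91.4% of the microRNAs tested above the L4440 range, whereas in T15H9.6 and hpo-31 only 24.0% and 22.1% were above it. No biological explanation other than loss of the target was tested, and these G tails make up the calls over all tails on gld-2 and pup-2 RNAi.

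The mir-35 family was lower on dis-3, exos-4.1, pap-1 and dcs-1 RNAi. A few microRNAs taking most of the counts are argued against, since the dis-3 family median was -4.87 with upper quartile scaling. Greater depth was tested 3 times: a first test over 22 other targets did not decide (rho -0.215, permutation p = 0.33), a second took the lowest family median among 11 targets as deep (-2.75) and would have favoured depth, and the last, chosen after the others were seen, took their median (-0.284) and argues against it. Fewer oocytes and embryos could lower both arms of each hairpin alike, and the medians of minor and dominant arms differed by at most 0.44 on dis-3, exos-4.1 and pap-1, but the arms of single hairpins by up to 2.20 (mir-41). With mir-42-3p not lower on dis-3 and exos-4.1 (1.25 and 1.76) and the medians 1.30 apart on dcs-1, this stays open in all 4, and a direct effect of these genes on the family stays untested.

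Minor arms such as mir-44-5p moved with the mir-35 family in sample group 4. Within groups of its 16 libraries mir-44-5p followed the family with r = 0.684 (permutation p = 0.0015, adjusted p = 0.0053, 14 such relations) and rho = 0.747, and r = 0.711 without the 2 farthest libraries, as a shared oocyte and embryo content may give, and in sample group 1 r was 0.569 (permutation p = 0.13, 11 libraries). Of 7 such arms only 4 followed the family past an adjusted p of 0.05 (r from 0.381 to 0.855), so shared content stays open for the set. The highest r was that of mir-39-5p, the other arm of a family hairpin, so its relation was given beforehand. mir-44 lies beside the family member mir-42 on chromosome II (11890023 to 11890118, same strand). Being encoded together was not tested for these arms and cannot be told apart from shared content. Depth stays open too, with r = 0.417 for mir-44-5p (permutation p = 0.23, 16 libraries), and over the 7 arms r from 0.379 to 0.665, with 4 at an unadjusted permutation p under 0.05 and 0 past the adjusted one. A biological effect of gldr-2 on minor arms stays untested.

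Some libraries lay far from the others of their group, which chance gives in about 1 of 20 groups, and 30 groups and measures were tested. In sample group 4 gldr-2 L4440 replicate 4 had 0.177% A tails (others 0.332% to 0.353%). Replicate 1 of gldr-2 with gld-2 RNAi had 0.384% G tails (others 0.0777% to 0.0906%). Wild-type L4440 replicate 1 had 4.57% over all tails (others 3.404% to 3.47%) and 1.34% G tails (others 0.0932% to 0.128%). Wild-type gld-2 RNAi replicate 2 had 0.119% G tails (others 0.0956% to 0.0993%). Screen L4440 replicate 4 had 4.52% over all tails (others 3.61% to 3.75%) and 0.116% G tails (others 0.135% to 0.138%).

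For mir-253-3p the 24 h change differed between F31C3.2 RNAi and L4440 by 9.10 points over all tails and 9.47 in U tails. It rests on 6 of 62 reads of 1 library.

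The effect of gld-2 RNAi on abundance differed between gldr-2 and wild type for 16 microRNAs. Of 100 splits of the samples 3 gave as many, the real one among them, and 1 of these called 68, several times the real count. Why that split called so many was not tested. These splits also break the pairs of gld-2 RNAi, and the count was 0 to 25 with 1 library left out, so whether chance gives the 16 stays open. Of the 35 splits for gldr-2, only the real grouping gave as many as 70, with a highest other of 30. That share is the smallest possible and is not adjusted for the many splits run, so chance is not excluded. Replicate numbers pair the libraries of gld-2 RNAi and of both, where 8 splits part every pair, too few for a share under 0.05. The real counts were 51 and 84, with highest others of 1 and 0, while the other splits leave pairs together. In tails too, only the real grouping of the 35 for gldr-2 gave its count over all, A and U tails (7, 16 and 4, highest others 1, 0 and 1). The same limit leaves chance open there. For gld-2 RNAi and both, with 8 such splits, the real counts were 2 and 9 over all tails, 3 and 16 in A tails and 5 and 13 in U tails, with highest others of 0 each. The interaction in tails was 0 over all, A and U tails, so that 100 of 100 splits are as large whatever they hold, which tests nothing, and highest others were 1, 15 and 2.

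With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In abundance pup-1, pup-2 and the double mutant gave 0, with highest others of 1, 0 and 10. In U tails they gave 10, 0 and 12 (highest others 0, 1 and 0), over all tails 0, 0 and 4 (1, 0 and 0) and in A tails 0 each (0 each). In tails the double mutant is paired, and 4 of the 10 splits part every pair (highest others 0 each). Its departure from the sum of single mutants had a real count of 0 in abundance and in each kind of tail, so that 100 of 100 splits are as large, which tests nothing, and highest others were 10 in abundance and 21, 1 and 7 over all, A and U tails. In sample group 5 the real counts were 0 for the lin-4 trigger (highest other 0), 51 for the mir-237 trigger (highest other 0) and 0 for the mir-85 trigger (highest other 0).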

How the results depend on the processing

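Among these the alternatives for sample group 5, merged identical counts, leaving out G tails, TMM on the libraries with spike-in reads, the prefix in tails and the table's own numbering were chosen only after seeing the result. The printed microRNAs are more stable than the set they come from. Of the 307 abundance results the naming rule gives, 188 kept their call whichever library was left out and 266 under every other setting, against 78 and 81 of the 83 printed. Of 284 tailing results that could be recomputed, 54.6% kept it without 1 library and 164 under other settings than the log2 scale, against 45 and 50 of the 61 printed, and 21 of the 1103 recomputed tailing values turned direction. Counting every printed microRNA, members of lists included, abundance kept its call in 487 of 517 refits without 1 library and in 542 of 553 other refits, and tails in 297 of 344 and 191 of 204. The count of called microRNAs stayed within 1.5 times in 140 of 181 refits in abundance, with 26 of 169 others outside, and in 319 of 414 and 279 of 332 in tails, and the lists kept their call in 20 of 74. mir-1020-3p at 48 h turned from 0.50 to -1.26 with spike-in scaling, which sets the total per spike-in read. mir-60-3p at 48 h went from 2.42 to -0.16 without 48 h replicate 1 and to 3.16 without 48 h replicate 2. The median of the mir-64 family at 24 h turned from 0.20 to -0.31 with upper quartile and -0.65 with spike-in scaling, and medians of other lists near 0 turned as well. For all of these the cause was not tested. A refit that leaves a group with 1 library assumes that it varies like the others. Spike-in scaling was not run for sample group 2, where no spike-in signal was used. In sample groups 1 and 2 only 2 pairs exist. Elsewhere, apart from gld-2 RNAi, both treatments and the double mutant in tails, numbers failed the pairing rule, so a block may not describe the design. In sample group 3 each replicate 1 lay apart on the second principal component of counts (-10.9 to -6.16, others 2.12 to 6.01), so a batch there stays open. In sample group 1 a library had as few as 283317 microRNA reads, so rare microRNAs rest on few reads there.

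Mean tail percents per library kept their call in 55 of 64 refits without 1 library and in 18 of 27 others, of which 1 turned direction. In A tails gldr-2 (-0.139) was -0.0974 without gldr-2 L4440 replicate 4, -0.162 without wild-type L4440 replicate 4, -0.0400 over the median microRNA and -0.139 with a replicate block, which changes only p. With both (-0.161) it was -0.131 without gldr-2 gld-2 RNAi replicate 4, -0.184 without wild-type L4440 replicate 4, -0.0415 over the median microRNA and -0.161 with the block. In U tails gld-2 RNAi in wild type (0.296) was 0.222 over pooled reads and 0.296 with the block. With both (0.280) it was 0.214 and 0.315 without gldr-2 gld-2 RNAi replicates 3 and 4, 0.117 over pooled reads, 0.280 with the block, and -0.0619 over the median microRNA. The count of screen targets with a call moved from 6 to 11 with the library prefix as a covariate. Under the mir-237 trigger the count of 51 was 19 without cdbEx29 replicate 2 and 73 without cdbEx32 replicate 1.

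In each pair of counts below the main analysis comes first. Without a filter on low counts the count in abundance moved for 6 h (11 to 20), 24 h on F31C3.2 RNAi (31 to 47), the cid-1 difference in the 24 h change (0 to 7), cid-1 RNAi at 0 h (3 to 22) and F31C3.2 RNAi at 0 h (0 to 14). It also moved for the gldr-2 and gld-2 interaction (16 to 10), dcs-1 RNAi in the screen (13 to 7) and xrn-1 RNAi in the screen (1 to 2). With upper quartile scaling the count in abundance moved for 6 h (11 to 6), cid-1 RNAi at 0 h (3 to 1), xrn-2 RNAi in the screen (8 to 13) and xrn-1 RNAi in the screen (1 to 2). With spike-in scaling the count in abundance moved for 48 h (77 to 122). That fit holds the pash-1 libraries alone and 202 microRNAs in place of 243, and TMM on the same set called 85, and mir-60-3p at 48 h was not called there (2.47). With DESeq2 the count in abundance moved for 24 h on F31C3.2 RNAi (31 to 54), the cid-1 difference in the 24 h change (0 to 2), cid-1 RNAi at 0 h (3 to 8), F31C3.2 RNAi at 0 h (0 to 1) and the pup-2 mutant (0 to 4). It also moved for dcs-1 RNAi in the screen (13 to 21). With a replicate block the count in abundance moved for gld-2 RNAi in wild type (51 to 79) and the gldr-2 and gld-2 interaction (16 to 26). Over all tails, with a replicate block, it moved for pash-1 at 0 h (7 to 4), 24 h on L4440 (3 to 1), 24 h on cid-1 RNAi (2 to 0), 24 h on F31C3.2 RNAi (3 to 1) and F31C3.2 RNAi at 0 h (2 to 0). It also moved for gldr-2 (7 to 17), gldr-2 with gld-2 RNAi (9 to 14) and pup-2 RNAi in the screen (43 to 0). In A tails, with a replicate block, it moved for pash-1 at 0 h (1 to 0), 48 h (4 to 0), gld-2 RNAi in wild type (3 to 9), gldr-2 with gld-2 RNAi (16 to 26) and the gldr-2 and gld-2 interaction (0 to 2). It also moved for cid-1 RNAi in the screen (4 to 1), F31C3.2 RNAi in the screen (11 to 1) and gld-2 RNAi in the screen (1 to 0). In U tails, with a replicate block, it moved for pash-1 at 0 h (9 to 4), 24 h on cid-1 RNAi (1 to 0), the F31C3.2 difference in the 24 h change (1 to 2), cid-1 RNAi at 0 h (4 to 1) and cid-1 RNAi in the screen (36 to 14). With the library prefix as a covariate the count in abundance moved for dis-3 RNAi in the screen (65 to 1.1e2 (45 higher, 61 lower)), exos-4.1 RNAi in the screen (49 to 77), pap-1 RNAi in the screen (47 to 83), xrn-2 RNAi in the screen (8 to 15) and xrn-1 RNAi in the screen (1 to 2). Over all tails, with the library prefix as a covariate, it moved for 24 h on L4440 (3 to 0), 24 h on cid-1 RNAi (2 to 0), 24 h on F31C3.2 RNAi (3 to 1) and F31C3.2 RNAi at 0 h (2 to 0). In U tails, with the library prefix as a covariate, it moved for 24 h on L4440 (5 to 3), 24 h on cid-1 RNAi (1 to 2), the F31C3.2 difference in the 24 h change (1 to 2) and pup-2 RNAi in the screen (0 to 1). On a log2 scale the count over all tails moved for 6 h (1 to 4), 24 h in sample group 1 (5 to 9), 24 h on cid-1 RNAi (2 to 0), the pup-1/-2 double mutant (4 to 2) and cid-1 RNAi in the screen (12 to 22). In U tails, on a log2 scale, it moved for 6 h (1 to 5), 24 h in sample group 1 (4 to 13), 24 h on L4440 (5 to 3), 24 h on F31C3.2 RNAi (7 to 4) and the F31C3.2 difference in the 24 h change (1 to 0). It also moved for cid-1 RNAi at 0 h (4 to 8), gldr-2 (4 to 8) and gld-2 RNAi in wild type (5 to 8). In A tails, on a log2 scale, it moved for cid-1 RNAi at 0 h (0 to 2), F31C3.2 RNAi at 0 h (1 to 4), F31C3.2 RNAi in the screen (11 to 17) and gld-2 RNAi in the screen (1 to 5). With G tails left out the count over all tails moved for 24 h on cid-1 RNAi (2 to 1), 24 h on F31C3.2 RNAi (3 to 6), F31C3.2 RNAi at 0 h (2 to 1), gld-2 RNAi in wild type (2 to 5) and cid-1 RNAi in the screen (12 to 28). It also moved for gld-2 RNAi in the screen (47 to 0) and pup-2 RNAi in the screen (43 to 0). The replicate block changed no other count by more than 1.5 times. It ended calls of single microRNAs in sample groups 1 and 2 and the screen, among them U tails of mir-70-3p at 24 h, of mir-71-5p at 24 h on cid-1 RNAi and of mir-38-3p, mir-56-3p and mir-35-3p on cid-1 RNAi at 0 h. The cause was not tested.

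Leaving out 1 library gave these lowest and highest counts (full count in brackets). In abundance, for 6 h (11) it was 1 without 0 h replicate 1 and 10 without 6 h replicate 2, and for 24 h in sample group 1 (69) it was 39 without 24 h replicate 1 and 66 without 24 h replicate 2. For 48 h (77) it was 36 without 0 h replicate 1 and 58 without 48 h replicate 2, and for 24 h on L4440 (44) it was 10 without L4440 0 h replicate 2 and 39 without L4440 24 h replicate 1. For 24 h on F31C3.2 RNAi (31) it was 8 without F31C3.2 RNAi 0 h replicate 2 and 15 without F31C3.2 RNAi 0 h replicate 1, and for the cid-1 difference in the 24 h change (0) it was 0 without L4440 0 h replicate 1 and 8 without cid-1 RNAi 0 h replicate 2. For the F31C3.2 difference in the 24 h change (0) it was 0 without F31C3.2 RNAi 0 h replicate 2 and 1 without F31C3.2 RNAi 0 h replicate 1, and for cid-1 RNAi at 0 h (3) it was 0 without L4440 0 h replicate 1 and 29 without cid-1 RNAi 0 h replicate 2. For F31C3.2 RNAi at 0 h (0) it was 0 without F31C3.2 RNAi 0 h replicate 2 and 1 without F31C3.2 RNAi 0 h replicate 1, and for the gldr-2 and gld-2 interaction (16) it was 0 without gldr-2 L4440 replicate 1 and 25 without wild-type L4440 replicate 3. For exos-4.1 RNAi in the screen (49) it was 30 without wild-type L4440 replicate 2 and 49 without wild-type L4440 replicate 1, and for dcs-1 RNAi in the screen (13) it was 5 without wild-type L4440 replicate 2 and 9 without wild-type L4440 replicate 1. Over all tails, for pash-1 at 0 h (7) it was 3 without 0 h replicate 2 and 6 without wild-type replicate 1, and for 6 h (1) it was 1 without 0 h replicate 1 and 2 without 6 h replicate 2. For 24 h in sample group 1 (5) it was 2 without 0 h replicate 1 and 3 without 24 h replicate 2, and for 48 h (18) it was 10 without 0 h replicate 2 and 24 without 48 h replicate 1. For 24 h on L4440 (3) it was 0 without L4440 0 h replicate 1 and 46 without L4440 24 h replicate 2, and for 24 h on cid-1 RNAi (2) it was 0 without cid-1 RNAi 0 h replicate 1 and 2 without cid-1 RNAi 0 h replicate 2. For 24 h on F31C3.2 RNAi (3) it was 1 without F31C3.2 RNAi 0 h replicate 2 and 3 without F31C3.2 RNAi 0 h replicate 1, and for the cid-1 difference in the 24 h change (0) it was 0 without L4440 0 h replicate 1 and 40 without L4440 24 h replicate 2. For the F31C3.2 difference in the 24 h change (1) it was 1 without F31C3.2 RNAi 0 h replicate 2 and 42 without L4440 24 h replicate 2, and for F31C3.2 RNAi at 0 h (2) it was 0 without F31C3.2 RNAi 0 h replicate 2 and 2 without F31C3.2 RNAi 0 h replicate 1. For the pup-1 mutant (0) it was 0 without pup-1 replicate 2 and 1 without pup-1 replicate 1, and for the pup-1/-2 double mutant (4) it was 1 without pup-1/-2 replicate 3 and 4 without pup-1/-2 replicate 2. For gld-2 RNAi in wild type (2) it was 1 without wild-type L4440 replicate 3 and 4 without wild-type L4440 replicate 1, and for the gldr-2 and gld-2 interaction (0) it was 0 without gldr-2 L4440 replicate 1 and 1 without gldr-2 L4440 replicate 2. For cid-1 RNAi in the screen (12) it was 7 without cid-1 RNAi replicate 1 and 17 without cid-1 RNAi replicate 2. In A tails, for pash-1 at 0 h (1) it was 0 without 0 h replicate 2 and 2 without wild-type replicate 1, and for 48 h (4) it was 0 without 0 h replicate 1 and 7 without 48 h replicate 1. For 24 h on cid-1 RNAi (0) it was 0 without cid-1 RNAi 24 h replicate 1 and 5 without cid-1 RNAi 0 h replicate 1, and for 24 h on F31C3.2 RNAi (0) it was 0 without F31C3.2 RNAi 0 h replicate 2 and 1 without F31C3.2 RNAi 0 h replicate 1. For the cid-1 difference in the 24 h change (0) it was 0 without L4440 0 h replicate 1 and 3 without cid-1 RNAi 0 h replicate 1, and for the F31C3.2 difference in the 24 h change (0) it was 0 without F31C3.2 RNAi 0 h replicate 2 and 1 without F31C3.2 RNAi 0 h replicate 1. For cid-1 RNAi at 0 h (0) it was 0 without L4440 0 h replicate 1 and 7 without cid-1 RNAi 0 h replicate 1, and for F31C3.2 RNAi at 0 h (1) it was 0 without F31C3.2 RNAi 0 h replicate 2 and 2 without F31C3.2 RNAi 0 h replicate 1. For gldr-2 (16) it was 10 without gldr-2 L4440 replicate 4 and 16 without wild-type L4440 replicate 4, and for the gldr-2 and gld-2 interaction (0) it was 0 without gldr-2 L4440 replicate 1 and 1 without gldr-2 L4440 replicate 4. For cid-1 RNAi in the screen (4) it was 1 without cid-1 RNAi replicate 2 and 4 without wild-type L4440 replicate 2, and for F31C3.2 RNAi in the screen (11) it was 1 without F31C3.2 RNAi replicate 1 and 11 without wild-type L4440 replicate 4. For gld-2 RNAi in the screen (1) it was 1 without wild-type L4440 replicate 1 and 2 without wild-type L4440 replicate 2. In U tails, for pash-1 at 0 h (9) it was 3 without 0 h replicate 1 and 6 without wild-type replicate 3, and for 24 h in sample group 1 (4) it was 2 without 0 h replicate 2 and 3 without 0 h replicate 1. For 48 h (18) it was 8 without 0 h replicate 2 and 15 without 48 h replicate 1, and for 24 h on L4440 (5) it was 2 without L4440 0 h replicate 2 and 7 without L4440 24 h replicate 1. For 24 h on cid-1 RNAi (1) it was 0 without cid-1 RNAi 24 h replicate 1 and 3 without cid-1 RNAi 0 h replicate 1, and for 24 h on F31C3.2 RNAi (7) it was 2 without F31C3.2 RNAi 0 h replicate 2 and 7 without F31C3.2 RNAi 0 h replicate 1. For the cid-1 difference in the 24 h change (0) it was 0 without L4440 0 h replicate 1 and 1 without L4440 24 h replicate 1, and for the F31C3.2 difference in the 24 h change (1) it was 1 without F31C3.2 RNAi 0 h replicate 2 and 5 without L4440 24 h replicate 2. For cid-1 RNAi at 0 h (4) it was 0 without L4440 0 h replicate 2 and 3 without cid-1 RNAi 0 h replicate 1, and for F31C3.2 RNAi at 0 h (0) it was 0 without F31C3.2 RNAi 0 h replicate 2 and 2 without F31C3.2 RNAi 0 h replicate 1. For gldr-2 (4) it was 2 without gldr-2 L4440 replicate 1 and 10 without gldr-2 L4440 replicate 4, and for gld-2 RNAi in wild type (5) it was 3 without wild-type gld-2 RNAi replicate 4 and 6 without wild-type gld-2 RNAi replicate 3. For gldr-2 with gld-2 RNAi (13) it was 7 without gldr-2 gld-2 RNAi replicate 1 and 12 without wild-type L4440 replicate 1, and for the gldr-2 and gld-2 interaction (0) it was 0 without gldr-2 L4440 replicate 1 and 1 without gldr-2 gld-2 RNAi replicate 3. For cid-1 RNAi in the screen (36) it was 10 without cid-1 RNAi replicate 1 and 31 without wild-type L4440 replicate 1, and for gld-2 RNAi in the screen (0) it was 0 without wild-type L4440 replicate 2 and 1 without wild-type L4440 replicate 1. Fewer libraries lower the power of each refit.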

Other observations

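The correlations of decay rate with tails were written before the result was seen, the relations between sets of libraries chosen after the changes were seen and the comparison of sample group 5 after the data were seen.

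In sample group 5, where arrays were meant to carry target sites that trigger decay and which the series calls inconclusive, 3 libraries per trigger were compared with 3 control libraries. Each set of 3 mixes 2 arrays, of which 1 gave 2 libraries, so n = 3 counts libraries and not arrays. mir-237-5p, of the lin-4 family, fell by 0.91 ± 0.23 under its own trigger (adjusted p = 0.00926, edgeR), from 4150 ± 483 to 2205 ± 617 CPM (SD, n = 3 each). lin-4-5p was at -0.13 ± 0.20 under the lin-4 trigger and mir-85-3p at -0.34 ± 0.19 under the mir-85 trigger, neither called. mir-237-5p itself was at -0.43 ± 0.22 under the mir-85 trigger (unadjusted p = 0.0687, edgeR) and -0.28 ± 0.22 under the lin-4 trigger, not called. Under the mir-237 trigger 51 of 279 microRNAs changed (38 higher, 13 lower), among them all 8 mir-35 family members, each higher (median 1.13), and minor arms. Why the family moved along with mir-237-5p was not tested. The count was 19 without control array replicate 2 of cdbEx29, and 30 and 29 without cdbEx33 replicates 1 and 2. The mir-237-5p call was lost without the first (-0.85) and the second (-0.83). edgeR called 0 for the lin-4 and mir-85 triggers, with 18 and 22 at an unadjusted p under 0.05 and 0 by DESeq2.

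The authors' decay table holds 70 microRNAs, of which 62 have a half-life under 1000 h, with a median of 18.04 h. The shortest were 2.23 h for mir-253-3p, 3.51 h for mir-250-3p, 4.63 h for mir-235-3p and 5.50 h for mir-230-3p, and 31 were over 24 h.

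A hypothesis was that microRNAs with more U tails at 0 h may decay faster, or those with more A tails slower. Across 70 microRNAs, which are not independent replicates, the authors' decay rate had a Spearman rho of -0.00912 with U tails (permutation p = 0.94) and 0.0958 with A tails (permutation p = 0.43). These leave both open, since whole animals and the authors' fitted rates limit the test.

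A hypothesis was that separate sets of libraries may share the microRNAs that each factor affects. The r of 0.840 for U tails (cid-1 RNAi and pup-1), 0.834 for A tails (F31C3.2 RNAi and gldr-2) and 0.752 for abundance at 24 h go with it. Falls are bounded by control tails, which favours a high r. Given these tails, partial r was 0.676 and 0.670, but partial rho was 0.0916 and -0.0985 (permutation p = 0.49 and 0.36). With pash-1 at 0 h in place of the mutants, partial rho was 0.55 and 0.33 (permutation p = 3e-05 and 0.005). Sharing beyond tail levels stays open for the mutants.

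G tails were also high outside the screen, at 3.99% in pup-1 replicate 2 and 1.46% in double-mutant replicate 2 of sample group 3, and 2.38% in L4440 24 h replicate 1 of sample group 2. In wild-type replicate 2 of sample group 1, mir-37-3p took 30.6% of microRNA counts.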
